A study of Mus musculus with 12 samples.

How the data were processed

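Tumours were grown from TRAMP-C2Re3 cells, a mouse prostate carcinoma line. Per the labels, 50000 cells were injected into the prostates of C57BL6 mice that were either wild type or knocked out for p62, and the tumours were taken after 60 days. The protein p62 is encoded by Sqstm1 and acts as an autophagy receptor and signalling adaptor. The injected cells carry their own Sqstm1, so that only host cells within a tumour lack it. Total RNA was extracted with TRIzol, amplified with the Ovation Pico WTA kit, labelled with biotin and hybridised to 1 single-colour array per tumour. There were 12 tumours, 6 from p62 KO hosts and 6 from wild-type hosts, each from a different mouse. The labels give no scan date, batch or RNA quality value.

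The deposited values are log2 intensities per probe set, and the submitters' processing notes name RMA (robust multi-array average, which corrects background, normalizes and summarises probes) without a version. The table had 34760 rows with no gaps. Its 6568 rows with the lowest identifiers carry no gene in the platform annotation and were taken as controls. This boundary was set from the identifiers after the table had been seen, and a test over all rows was added for that reason. The remaining 28192 probe sets were tested, of which 21640 have 1 gene symbol, 1321 have several and 5231 have none in the annotation used. Probe sets with several symbols were not named. Updating symbols through Entrez identifiers changed 0 of them. A gene stood for its probe set with the highest mean over the 12 tumours, which applied to 954 of 19937 genes with several probe sets. Arrays have no counting depth, and their number limits the precision. Detection calls were not used here, so that levels near the low end of the scale cannot be set against background.

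Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no covariate), with Benjamini-Hochberg adjustment over the tested probe sets and a threshold of adjusted p under 0.05. Differences are given as log2 of p62 KO hosts minus wild-type hosts. The label check on Sqstm1 used an exact two-sided permutation test over all 924 assignments of the 12 tumours. Before the data were examined, 37 gene lists were fixed, covering the IL-6, NF-kB and TGF-beta pathways, stroma, metabolism, proliferation, cell type markers and technical signs such as tissue-handling genes and genes near Sqstm1. Of their 871 genes, 801 were measured. The 35 lists with at least 5 measured genes were tested with camera from limma at its preset inter-gene correlation of 0.01, adjusted over lists, and the erythroid and Y-linked lists were only described. Members of a list were also adjusted over the list alone. The rule for named genes was fixed at the same time. It takes Sqstm1, then 12 probe sets in each direction, those passing the threshold first by size and then those with the smallest unadjusted p, and for each list its preset anchor genes and up to 4 members with the smallest unadjusted p. Genes named outside that rule are said to be.

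The test was tried on simulated data with known changes added to the arrays' own residuals. It recovered 18% of changes of 0.5 on the log2 scale, 82% of changes of 1, 94% of changes of 2 and 100% of changes of 3, with 0 false calls. Independent noise gave 28%, 78%, 100% and 98%, with 8 false calls. The residuals average 0 within each host group, so that unchanged probe sets differed by 0 and the 0 false calls were fixed in advance. Their recovery rates carry no error of the estimated difference either. Only the independent noise bears on false calls. It holds none of the correlation between probe sets or differences between arrays seen in the data. Its 8 false calls therefore do not give the number to be reckoned with in these tumours.

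Alternatives fixed in advance were a common median per array, quantile normalization, a filter on dim probe sets, 1 probe set per gene, the mean of all probe sets of a gene, eBayes with trend and robust, array weights, the mouse number as a block, a score of gland secretion genes as a covariate, each tumour left out in turn, other thresholds, camera with an estimated correlation, and fry. A change of log scale was not run because the values already are on a log2 scale. Further alternatives were chosen after the values had been seen. They are the omission of KO hosts 2 and 3, the omission of these with wild-type hosts 2 and 5, each array's interquartile range as a covariate, a test over all rows of the table, and an exact permutation test of each list's mean level per tumour. Plots were drawn with matplotlib 3.10.9.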

Results

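The series compared prostate tumours grown in hosts without p62 with tumours of the same injected cells grown in wild-type hosts, which asks whether loss of p62 in the host alters the RNA of the whole tumour. Expression was measured on 12 arrays, 6 per host genotype. Pairwise correlations between arrays lay between 0.935 and 0.991. The first principal component held 58.5% of the variance, and its 4 highest scores belonged to KO hosts 2 and 3 and wild-type hosts 2 and 5. The same 4 arrays had the narrowest interquartile ranges, 2.26, 2.15, 2.59 and 2.47, against 2.70 to 2.95 for the other 8. Since KO hosts 2 and 3 were the farthest apart, some results are also given without them. This omission is unbalanced, because wild-type hosts 2 and 5, with scores of 17.2 and 29.0 on the same side, stay in. Results without KO hosts 2 and 3 therefore set KO tumours with wider ranges against a wild-type group that keeps its narrowest arrays. Many differences changed relative to their own size when each tumour was left out in turn. At least once, 109 of 189 entries and 31 of 37 lists turned direction or changed by more than a factor of 1.5. The 189 entries are the probe sets taken by the rule for named genes plus the counts of lists called higher and lower. The count of lists called lower is among the 109. The factor compares log2 differences, so that a small difference can pass it with a small shift. Sqstm1 passed it, at -0.16 over all tumours and -0.05 without KO host 2.

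**Figure D1:**
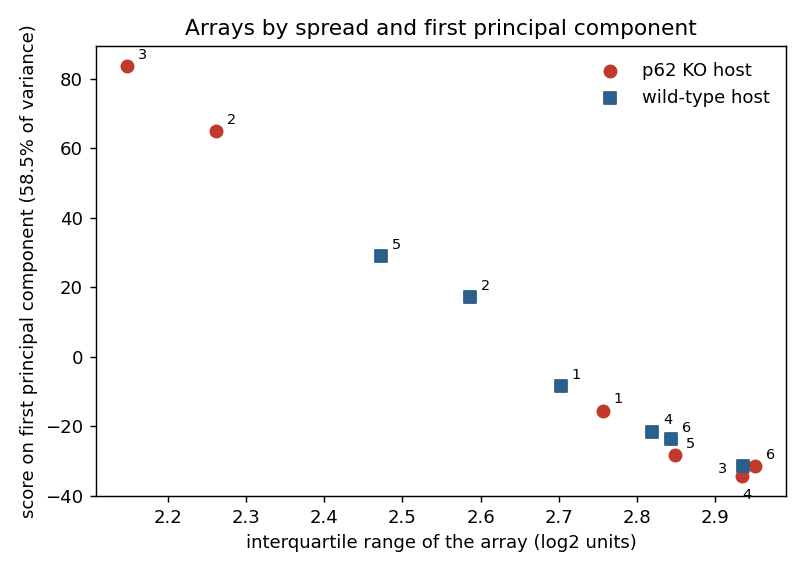
Each point is 1 array, numbered by mouse, with the interquartile range of its log2 values on the horizontal axis and its score on the first principal component (58.5% of variance, no unit) on the vertical axis. KO hosts 3 and 2 have the highest scores, 83.6 and 65.0, and the narrowest ranges, 2.15 and 2.26.

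Sqstm1, which encodes p62, had a log2 level of 8.73 ± 0.39 (SD, n = 6) in tumours of KO hosts and 8.89 ± 0.23 (SD, n = 6) in tumours of wild-type hosts. The difference of -0.16 had a 95% interval of -0.53 to 0.21 and an exact permutation p of 0.42, and it turned to 0.05 without KO hosts 2 and 3 (adjusted p = 0.913). This level does not check the genotype labels, because the injected cells carry their own Sqstm1 and the exons deleted in the hosts are not given, so that host cells may still transcribe the rest.

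A single probe set passed the threshold, that of Nlrp1c-ps, a pseudogene of the Nlrp1 family of inflammasome sensors. Its log2 level was 5.33 ± 0.29 (SD, n = 6) in tumours of KO hosts and 7.01 ± 0.48 (SD, n = 6) in tumours of wild-type hosts, a difference of -1.68 (SE 0.21, adjusted p = 0.0378) or 3.20-fold. All 6 tumours of KO hosts lay below all 6 of wild-type hosts. Its family members Nlrp1a, at 4.74 against 5.41, and Nlrp1b, at 5.54 against 5.87, differed by -0.67 (SE 0.16) and -0.33 (SE 0.10) without passing (adjusted p = 0.9935 each). Nlrp1b was chosen after its values were seen. Copies of this family are similar in sequence, and signal shared between their probe sets was not tested. The Nlrp1c-ps call was kept without KO host 2 (adjusted p = 0.0456) and without wild-type host 2 (0.00143), and was lost in the other 10 leave-outs, at adjusted p of 0.0846 to 0.173, while the difference stayed between -1.85 and -1.58. It was also lost without KO hosts 2 and 3 together (adjusted p = 0.108), with the level of gland secretion genes as a covariate (adjusted p = 0.0616) and when all rows of the table were tested (adjusted p = 0.0656). The mouse number as a block ended it too (smallest adjusted p of any probe set 0.999), although the labels do not say that these numbers pair the tumours. The filter on dim probe sets removed this probe set.

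Across the 28192 probe sets, limma called 0 higher and 1 lower in tumours of KO hosts. At an unadjusted p under 0.05 there were 362 higher and 313 lower, together 675 or 2.39%, against a nominal 5%. Levels are correlated between probe sets, and 36 of 100 splits of the 12 tumours into 6 and 6, the real one included, had at least as many, with a median of 504 in the others. The share under 0.05 rose to 7.72% without KO hosts 2 and 3 and to 5.09% without these and wild-type hosts 2 and 5. It was 6.85% with the interquartile range as a covariate and 6.52% with array weights. In the other settings tried it stayed below 5%, between 1.54% and 3.58%. The groups did not overlap in 41 probe sets, or 0.145%, where chance gives 0.216% on average.

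None of the genes with the smallest unadjusted p in the higher direction passed (adjusted p = 0.9935 for each). Cxcl2, a neutrophil-attracting chemokine, stood at 6.59 ± 0.65 against 5.63 ± 0.26, a difference of 0.95 (SE 0.25). Egln3, a hypoxia-induced prolyl hydroxylase, differed by 0.91 (SE 0.25), Atp6v0d2, a subunit of the vacuolar proton pump, by 0.85 (SE 0.23) and Higd1a, a hypoxia-inducible mitochondrial protein, by 0.71 (SE 0.16). The B cell receptor gene Cd79a differed by 0.63, the coagulation initiator F3 by 0.48, and the mesenchymal regulator Twist2 and the cytokine Mif by 0.46 each. Lep, which encodes leptin, differed by 0.41, Pirb by 0.39, and Itgb3 and Ankrd37 by 0.34 each. The levels of Cd79a, 5.05 and 4.42, and of Lep, 4.95 and 4.54, lie near or below the lower quartiles of the arrays, 4.85 to 5.36.

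After Nlrp1c-ps, the genes with the smallest unadjusted p in the lower direction did not pass either (adjusted p = 0.9935 for each besides Nlrp1c-ps). Adcyap1r1, a neuropeptide receptor, differed by -0.90 (SE 0.22). Greb1l differed by -0.63, 2610005L07Rik by -0.56, Etfbkmt by -0.55 and the microRNA gene Mir374b by -0.54. The bile acid transporter Slc10a1 differed by -0.45, the cysteine dioxygenase Cdo1 by -0.44, Zfp398 by -0.42, Dnajb7 by -0.36 and Gimap8 by -0.31. The levels of Mir374b, 3.10 and 3.65, lie below the lower quartiles of the arrays, 4.85 to 5.36. Those of 2610005L07Rik, 4.76 and 5.32, lie near or below them.

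**Figure D2:**
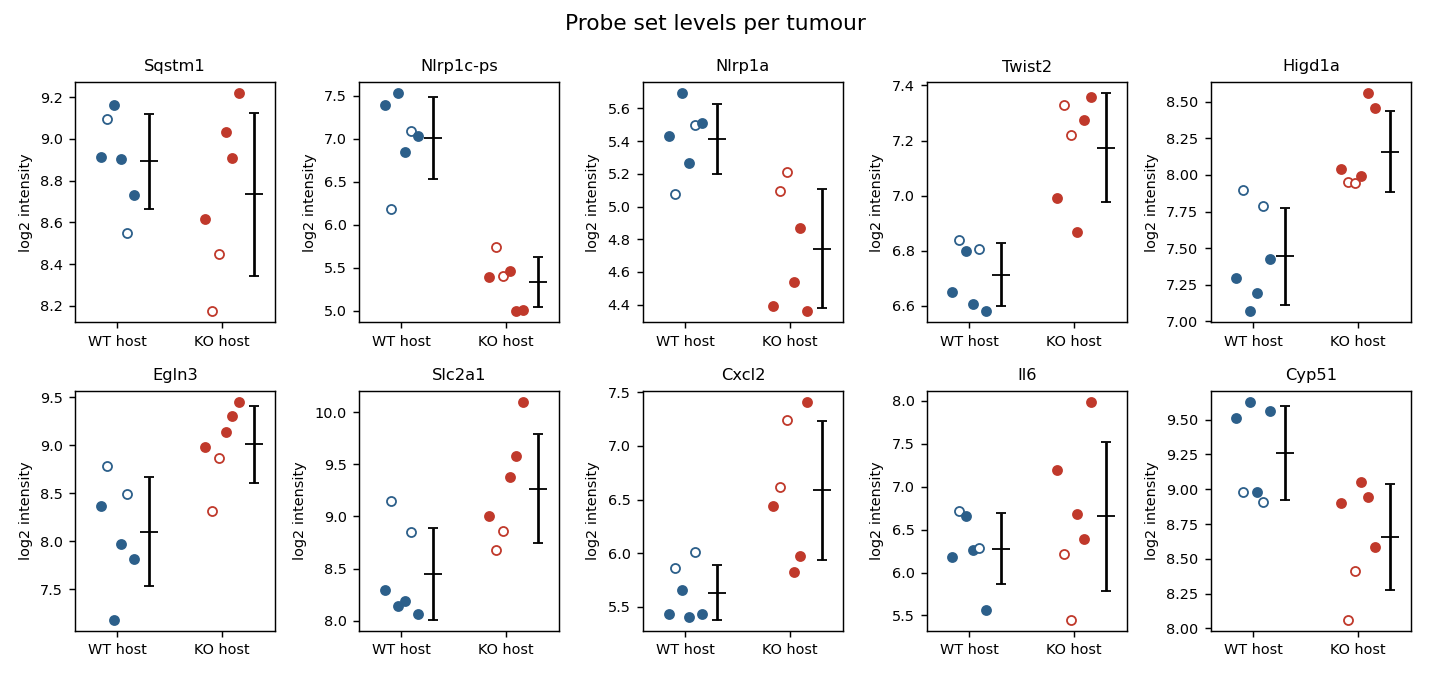
Log2 intensity of 10 probe sets in each tumour, with wild-type hosts in blue and p62 KO hosts in red; open circles mark KO hosts 2 and 3 and wild-type hosts 2 and 5, and bars show mean and SD. Nlrp1c-ps lies between 4.99 and 5.75 in KO hosts and between 6.18 and 7.53 in wild-type hosts, and Sqstm1 and Il6 overlap.

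The largest mean difference among the lists was that of hypoxia response genes. The 25 hypoxia and angiogenesis genes averaged 8.26 ± 0.30 in tumours of KO hosts and 7.90 ± 0.22 in tumours of wild-type hosts, a difference of 0.36, and 20 of them were higher. Higd1a, Ankrd37, Egln3, the glucose transporter Slc2a1 and the stress-responsive Ndrg1 were the 5 members that passed when adjusted over the list alone (adjusted p = 0.0176 to 0.0436), while 0 passed over all probe sets. Ndrg1 lies outside the rule for named genes and was chosen after its value was seen. Vegfa, the main angiogenic factor, differed by 0.30 (SE 0.18) without passing. The list was called by camera (adjusted p = 1.15e-09), and this call was lost with an estimated correlation (adjusted p = 0.595).

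The 19 glycolysis genes averaged 8.72 ± 0.25 against 8.48 ± 0.15, a difference of 0.25, with 16 higher. Slc2a1, at 9.27 ± 0.53 against 8.45 ± 0.44, the aldolase Aldoc and the lactate exporter Slc16a3 were the 3 that passed when adjusted over the list alone (adjusted p = 0.0454 each), and 0 passed over all probe sets. Pfkl differed by 0.45 without passing. Camera gave an adjusted p of 2.5e-07, and the adjusted p was 0.595 with an estimated correlation. The hypoxia and glycolysis lists share Slc2a1, Pdk1 and Pfkfb3. Without KO hosts 2 and 3 their differences were 0.51 and 0.37.

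Neutrophil markers averaged 6.10 ± 0.27 against 5.83 ± 0.19, a difference of 0.27, with 19 of 21 higher and 0 passing over the list alone. S100a9 differed by 0.58, Trem1 by 0.55, Ly6g by 0.44 and S100a8 by 0.43. The levels of Ly6g, 4.10 to 5.40 over the tumours, and of Trem1, 4.62 to 6.18, reach below the lower quartiles of the arrays, 4.85 to 5.36. KO hosts 2 and 3 were the highest tumours in Ly6g (5.05 and 5.40) and in S100a8 (6.51 and 6.06). Without KO host 3 Ly6g differed by 0.30, and without KO host 2 S100a8 differed by 0.28. Camera called the list (adjusted p = 1.6e-06, or adjusted p = 0.595 with an estimated correlation). KO hosts 2 and 3 had the 2 highest levels, 6.36 and 6.35, and without them the difference was 0.15 and not called (adjusted p = 0.0821). Among 35 inflammatory cytokines and chemokines the mean difference was 0.14, with 24 higher and 0 passing over the list alone. Besides Cxcl2, Cxcl3 differed by 0.68, Ccl3 by 0.63 and Ccl2 by 0.41, whereas Il1b (0.37, SE 0.34), Cxcl1 (0.27, SE 0.20) and Tnf (0.03, SE 0.13) had unadjusted p above 0.05. This list was called (adjusted p = 0.0036, or adjusted p = 0.66 with an estimated correlation) but not without KO hosts 2 and 3, at a difference of 0.09 (adjusted p = 0.268), while Ccl2 and Ccl3 were then at 0.57 and 0.75 without passing (adjusted p = 0.638 each).

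Il6 itself stood at 6.65 ± 0.87 against 6.28 ± 0.41, a difference of 0.38 (SE 0.34) that did not pass. Leaving out KO hosts 2 and 3 gave 0.79 (adjusted p = 0.638) and leaving out KO host 6, the highest at 7.99, gave 0.11 (adjusted p = 0.934), neither passing. The 31 genes of the IL-6 and STAT3 list differed by 0.08 on average and were not called (adjusted p = 0.101). Socs3, a feedback target of STAT3, differed by -0.01, Lif by 0.25, Pim1 by 0.17, Jak2 by -0.33 (-0.08 without KO hosts 2 and 3) and the acute-phase gene Lcn2 by 0.79 (SE 0.41). The 22 NF-kB genes differed by 0.08 (adjusted p = 0.101), with Nfkbia at 0.28 and Ier3 at 0.51. Without KO hosts 2 and 3 the NF-kB list was called higher, at a difference of 0.12 (adjusted p = 0.0185), but not with an estimated correlation (adjusted p = 0.566). The 28 TGF-beta genes differed by 0.0038 on average, with camera pointing down because this lies below the mean of other genes (adjusted p = 0.605). Tgfb1 differed by 0.04 (SE 0.14), Pmepa1 by -0.27 and Ccn2 by 0.36.

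The lists of fibroblast, contractile and matrix genes were not called over the 12 tumours. The 24 fibroblast markers differed by -0.03 (adjusted p = 0.46), with Fap at -0.27 (SE 0.28) and Pdgfra at 0.01 (SE 0.25). The list turned to 0.04 without KO hosts 2 and 3 (adjusted p = 0.638), and Pdgfra was at 0.34, neither passing. The 17 contractile genes differed by 0.03 (adjusted p = 0.525), with the myofibroblast actin Acta2 at -0.07 (SE 0.14). The 35 collagen and matrix genes differed by 0.07 (adjusted p = 0.34), with Col1a1 at -0.03 (SE 0.09). The collagen list was called higher without KO hosts 2 and 3, at a difference of 0.12 (adjusted p = 0.0015, or adjusted p = 0.664 with an estimated correlation). The 23 autophagy genes differed by -0.03 (adjusted p = 0.38), with Map1lc3b at 0.02 (SE 0.15), and were called higher without KO hosts 2 and 3 (0.09, adjusted p = 0.00962, or adjusted p = 0.664 with an estimated correlation). The 14 genes of mesenchymal transition had a mean of -0.02 and a median of 0.01 (adjusted p = 0.994), and Twist2 alone passed over that list (adjusted p = 0.0076).

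Camera called 6 lists lower. The 26 sterol and fatty acid synthesis genes averaged 7.76 ± 0.28 against 7.99 ± 0.25, a difference of -0.22 with 21 lower and 0 passing over the list alone (adjusted p = 2.5e-07, or adjusted p = 0.657 with an estimated correlation). Cyp51 of sterol synthesis stood at 8.66 ± 0.38 against 9.26 ± 0.34, Hmgcs1 differed by -0.45, the desaturase Scd1 by -0.43 and Fads2 by -0.33. The mTORC1 and ATF4 list differed by -0.12 with 26 of 30 lower (adjusted p = 0.000212, or adjusted p = 0.687 with an estimated correlation), and its cystine transporter Slc7a11 by -0.78 (SE 0.35), or -0.46 without wild-type host 2. Interferon-stimulated genes differed by -0.12 with 24 of 31 lower (adjusted p = 0.00126, or adjusted p = 0.687 with an estimated correlation), among them Ifit1 at -0.43 and Oas2 at -0.33. KO host 4 was the highest of its group in this list, and without it the difference was -0.24. Glutamine metabolism differed by -0.13 with 14 of 18 lower (adjusted p = 0.00866, or adjusted p = 0.687 with an estimated correlation), with Gclc at -0.57 and Glul at 0.25. Cell cycle genes differed by -0.07 with 28 of 38 lower (adjusted p = 0.0213, or adjusted p = 0.752 with an estimated correlation), with Mki67 at -0.07 and Mad2l1 at -0.24. Myc targets differed by -0.05 with 20 of 32 lower (adjusted p = 0.0422, or adjusted p = 0.691 with an estimated correlation), while Myc itself differed by 0.20 (SE 0.13).

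KO hosts 2 and 3 had the lowest levels of several of these lists. Without them 0 of the 6 were called lower, and the glutamine, Myc and cell cycle lists turned to differences of 0.08, 0.05 and 0.12, the last of them called higher (adjusted p = 0.000297, or adjusted p = 0.679 with an estimated correlation). Wild-type host 5, which stayed in, was the lowest of its group in the glutamine, Myc and cell cycle lists (8.74, 9.24 and 8.65). The sterol list was at -0.05 (adjusted p = 0.342) and the mTORC1 and ATF4 list at -0.0023 (adjusted p = 0.874). Interferon-stimulated genes stayed at -0.09 with 7 of 31 higher, as over all 12 tumours (adjusted p = 0.214), so that the lost call does not put their difference down to KO hosts 2 and 3.

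Camera also called 5 further lists higher. Adipocyte markers differed by 0.18, with Lep the 1 member passing over the list alone (adjusted p = 0.0439), Cd36 at 0.70 (SE 0.38) and Fabp4 at 0.57 (SE 0.34), or 0.34 and 0.25 without wild-type host 4, the lowest in both. Plin1 differed by 0.17 and Adipoq by 0.08, the latter between -0.03 and 0.18 over the leave-outs. The call of the adipocyte list had an adjusted p of 0.000525, or an adjusted p of 0.657 with an estimated correlation. Macrophage markers differed by 0.12 (adjusted p = 0.0315), with Arg1 at 0.82 (SE 0.48), Itgam at 0.30 and Adgre1 at -0.13. Endothelial markers differed by 0.10 (adjusted p = 0.00973), with Sox17 at 0.28 and Pecam1 at -0.04, and skeletal muscle markers by 0.09 (adjusted p = 0.0292), with Des at 0.21 and Ckm at 0.03. Each of these 3 had an adjusted p of 0.687 with an estimated correlation. Without KO hosts 2 and 3 the adipocyte and skeletal muscle lists were not called, at 0.08 and 0.0065 (adjusted p = 0.522 and 0.847). The macrophage and endothelial lists were then at 0.20 (adjusted p = 0.00126, or adjusted p = 0.664 with an estimated correlation) and 0.16 (adjusted p = 0.0015, or adjusted p = 0.679 with an estimated correlation), and Adgre1 and Pecam1 turned to 0.27 and 0.37 without passing. Wild-type hosts 2 and 5, which stayed in, were the lowest of their group in Adgre1 (9.10 and 9.55) and Pecam1 (7.55 and 7.88). The values of both genes therefore also depend on these wild-type tumours. Immediate early and heat shock genes, which respond to tissue handling, differed by 0.13 (adjusted p = 0.0292, or adjusted p = 0.66 with an estimated correlation), with Dusp1 at 0.56, Nr4a1 at 0.45 and Fos at 0.29. Their difference without KO hosts 2 and 3 was 0.20 (adjusted p = 0.012, or adjusted p = 0.664 with an estimated correlation).

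**Figure D3:**
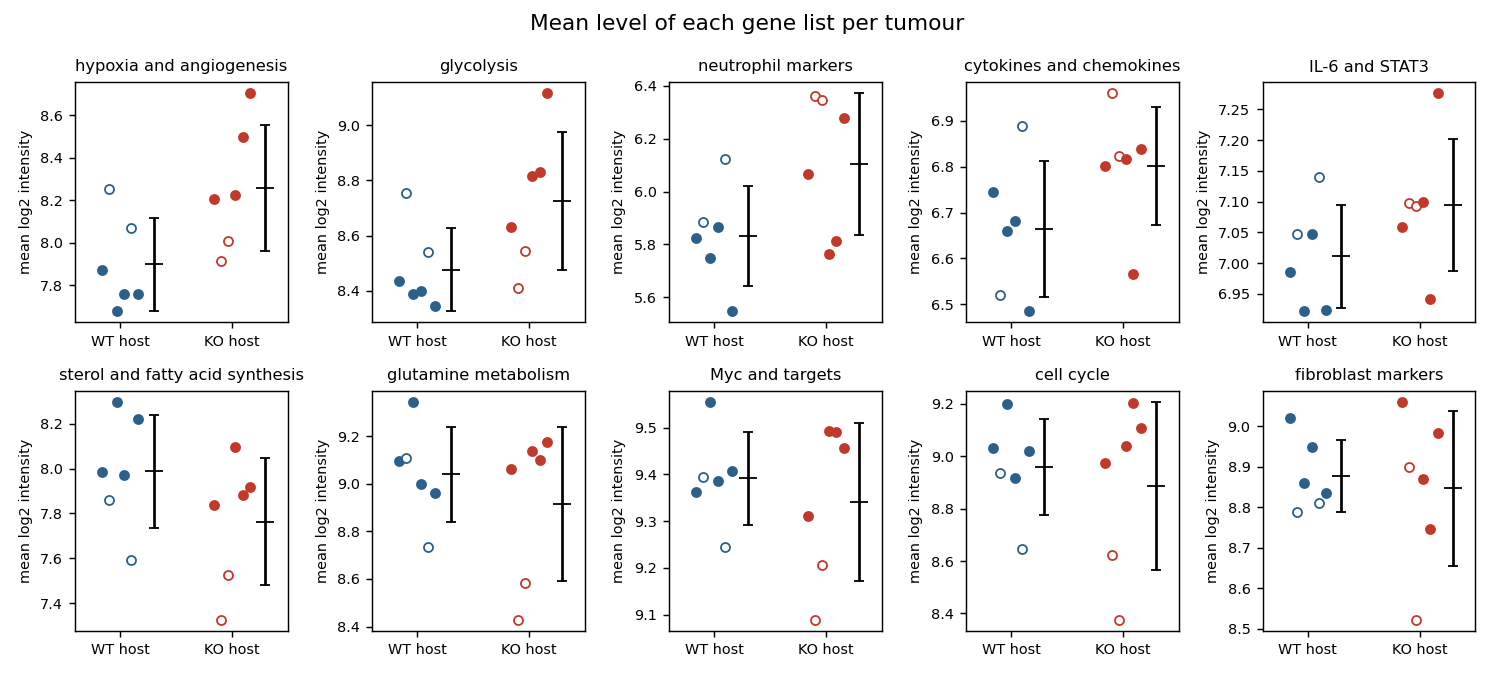
Mean log2 intensity of the measured genes of 10 lists in each tumour, with wild-type hosts in blue and p62 KO hosts in red; open circles mark KO hosts 2 and 3 and wild-type hosts 2 and 5, and bars show mean and SD. In the sterol, glutamine, Myc and cell cycle lists KO hosts 2 and 3 are the lowest tumours of their group, as in the hypoxia and glycolysis lists, where the group mean is higher.

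In all, 9 lists were called higher and 6 lower with the preset correlation, and 0 in either direction with an estimated correlation, with fry or with exact permutation of the list means per tumour. The smallest exact permutation p was 0.0411, for the hypoxia list, or 0.644 after adjustment over lists. Without KO hosts 2 and 3, 11 lists were called, of which 5 were among the 15 and in the same direction, and 0 were called with an estimated correlation (smallest adjusted p = 0.401).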

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

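The tests on the 4 tumours standing apart were written before their results were seen, and the reading of the marker test was changed afterwards, as said there. Of 122 groups of 6 values examined, 8 had a tumour far from the other 5 of its group, and chance gives about 1 in 20. In KO host 1 Cd79a was lowest at 4.58 (next 5.05) and Cdo1 highest at 7.42 (next 7.17), each toward the wild-type level. Mif was highest in KO host 6, at 10.79 against 10.35 for the next tumour. The respiratory chain list was lowest in KO host 3 at 8.50 (next 8.89), and so was the macrophage list at 8.26 (next 8.58). The interferon list was highest in KO host 4 at 8.08 (next 7.44), although its group mean lay below that of wild-type hosts. In wild-type host 2 endothelial markers were lowest at 6.58 (next 6.83) and neuroendocrine markers highest at 5.83 (next 5.72).

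KO hosts 2 and 3 and wild-type hosts 2 and 5 held the 4 highest scores on the first principal component, which held 58.5% of the variance. Their narrower spread of values is not the whole account, since after quantile normalization, which gives each array the same spread, the component still held 52.6% and the same 4 tumours had its highest scores. RNA of another cell type may contribute: against 10000 level-matched random lists, no marker list passed the upper limit set in advance in all 4 tumours (the best, prostate epithelium, reached a lowest percentile of 88.19), but neutrophil markers did in KO host 2 (100), KO host 3 (99.9) and wild-type host 5 (99.8), and not in wild-type host 2 (46.3). S100a9, the neutrophil gene named with the highest level, stood at 7.13 and 7.23 in KO hosts 2 and 3 but also at 7.33 in KO host 1, which does not stand apart. The bound set in advance asked for 1 list in all 4 tumours, which was too strict because tumours can hold different cells, so this explanation is left open. A loss of signal from poor RNA or amplification also stays open, as the labels give no RNA quality and none was tested.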

How the results depend on the processing

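The omissions of KO hosts 2 and 3 and of these with wild-type hosts 2 and 5, the interquartile range as a covariate, the test over all rows and the permutation of list levels were chosen after seeing the data. The 1 probe set called lower became 0 with the filter on dim probe sets (which removes Nlrp1c-ps), the mouse number as a block, the gland secretion covariate, KO hosts 2 and 3 omitted, and all rows tested, and ranged from 0 to 1 over the leave-outs. The labels do not say that mouse numbers pair the samples. A number's own partner correlated best in 0 of 6 cases, at correlations of -0.54 to 0.31. So few pairs cannot exclude an order or batch shared by tumours of the same number. At an unadjusted p under 0.05 and at least 1.5-fold there were 34 probe sets higher and 39 lower. The number of lists called lower, 6, became 3 with quantile normalization, the dim filter, the gland covariate, all 4 tumours omitted or the interquartile range covariate, became 1 with KO hosts 2 and 3 omitted (T and NK cells, not among the 6), and ranged from 2 to 7 over the leave-outs. Lists called higher and lower were both 0 with an estimated correlation, with fry and with exact permutation. Sqstm1 moved from -0.16 to 0.017 with array weights, 0.053 without KO hosts 2 and 3 and 0.017 without all 4, passing in none.

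List differences below are relative to all other genes and given for lists called in at least 1 of the 2 settings compared. Of lists called in neither, 8 more turned with array weights, 11 without KO hosts 2 and 3 and 10 without all 4, and up to 7 in each other setting. With array weights the direction turned for Myc targets (0.035), glutamine (0.035), respiratory chain (0.067), autophagy (0.068) and cell cycle (0.080). Without KO hosts 2 and 3 it turned for Myc targets (0.045), mTORC1 and ATF4 (-0.0037, where camera pointed up), glutamine (0.077), respiratory chain (0.091), autophagy (0.093), cell cycle (0.12) and skeletal muscle (0.0050, where camera pointed down). Without all 4 it turned for glutamine (0.015) and cell cycle (0.036). Over the leave-outs the respiratory chain ranged from -0.061 to 0.070 and cell cycle from -0.14 to 0.030, each turning without KO host 3. Array weights and the omissions give KO hosts 2 and 3 less or no weight, and for the other settings the cause was not tested.

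Of the 15 called lists, hypoxia and glycolysis were the 2 called in all 24 other settings that used camera with the preset correlation. Leaving out 1 tumour ended the call of mTORC1 and ATF4 (KO host 2, adjusted p = 0.105), glutamine (KO hosts 2 and 3 and wild-type host 3, 0.401, 0.239 and 0.223), skeletal muscle (the same 3, 0.105, 0.35 and 0.116), endothelium (KO hosts 5 and 6 and wild-type host 2, 0.187, 0.127 and 0.329), and of cell cycle, Myc, early response genes (5 tumours each) and macrophages (7 tumours), at adjusted p up to 0.477, 0.605, 0.153 and 0.385. Detection above background was not used here, so that differences of dim probe sets are open to compression.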

Other observations

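The tests of KO hosts 2 and 3 as the source of a difference and of a strain segment were chosen after the results they bear on had been seen. Genes of MHC class II presentation varied more between tumours than between hosts. H2-Aa stood at 8.95 ± 1.20 (SD, n = 6) in tumours of KO hosts and 9.36 ± 1.57 in tumours of wild-type hosts, and ranged from 6.49 in wild-type host 2 to 10.76 in wild-type host 1. Cd74, the invariant chain, followed with 6.00 and 9.85 in the same tumours. The list differed by -0.18, or 0.02 without KO hosts 2 and 3, and was not called (adjusted p = 0.293 and 0.871). Leaving out 1 tumour moved it between -0.49 (wild-type host 2) and -0.0089 (wild-type host 1). It was called lower without wild-type host 2 (adjusted p = 0.00156, or adjusted p = 0.685 with an estimated correlation) and without KO host 4 (adjusted p = 0.0425, or adjusted p = 0.669 with an estimated correlation). T and NK cell markers differed by 0.0026 on average (adjusted p = 0.994, camera pointing down), with Cd3e at -0.14 and Cd8a at -0.15, and were the 1 list called lower without KO hosts 2 and 3 (-0.09, adjusted p = 0.0114, or adjusted p = 0.679 with an estimated correlation). B and plasma cell markers differed by 0.07 (adjusted p = 0.0616), with Cd79a the 1 member passing over the list alone (adjusted p = 0.004). The B and plasma cell list was at -0.02 without KO hosts 2 and 3, with 5 of 18 higher (adjusted p = 0.607). Mast and dendritic cell markers differed by -0.0028 (adjusted p = 0.799).

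NRF2 targets went both ways. Gstp1 (0.78, SE 0.26) and Hmox1 (0.63, SE 0.24) were higher in tumours of KO hosts and Nqo1 (-0.60, SE 0.26) and Gclc (-0.57, SE 0.20) lower, none passing even over the list alone, and the list differed by -0.02 (adjusted p = 0.59). The respiratory chain differed by -0.0087 (adjusted p = 0.555), turning to 0.09 without KO hosts 2 and 3 (adjusted p = 0.0111, or adjusted p = 0.679 with an estimated correlation), and the pentose phosphate pathway by -0.06 (adjusted p = 0.525). Prostate epithelium markers differed by 0.09 and neuroendocrine markers by 0.06 (adjusted p = 0.0616 each), gland secretion genes by 0.05 (adjusted p = 0.187) and ribosomal proteins by 0.06 (adjusted p = 0.131). The 27 genes near Sqstm1 differed by 0.0052 on average with a median of -0.005 (adjusted p = 0.893). The 3 erythroid genes differed by -0.0065, with a median of 0.0082, and the 3 Y-linked genes by 0.01. The Y-linked levels were lowest in the tumours standing apart, at 5.86 and 5.43 in KO hosts 2 and 3 and 5.45 and 6.13 in wild-type hosts 2 and 5. The next lowest was wild-type host 1, at 6.27. This was seen afterwards and its cause was not tested.

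Of 100 splits of the 12 tumours into 6 and 6, the real one included, 14 called at least as many lists as the real 15, and the highest other split called 19, so that chance is not excluded for the number of called lists. For probe sets, 2 of the 100 called at least 1, the highest other calling 3. The adjusted threshold itself keeps calls rare under chance, so that this largely repeats the call. That call was kept in 2 of 12 leave-outs and lost when all rows were tested (adjusted p = 0.0656). Chance is therefore not excluded for the count of 1 either. A split with 10232 probe sets at an unadjusted p under 0.05, against 675 for the real one, points to a structure among the tumours other than host genotype.

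The 41 genes of the hypoxia and glycolysis lists averaged 8.48 ± 0.27 in tumours of KO hosts and 8.17 ± 0.18 in tumours of wild-type hosts, a difference of 0.31 (exact permutation p = 0.0411, not adjusted for having been picked from 35 lists). The outlying KO hosts 2 and 3 had the lowest levels of their group, 8.16 and 8.27, so that omitting them could only raise the difference. It was 0.44 without them (exact permutation p = 0.0143, likewise not adjusted), which is no separate test of these tumours. With the interquartile range as a covariate the difference was 0.33 (95% interval 0.041 to 0.624), so that a relation to spread shared by both groups does not account for it. The covariate fits 1 slope to both groups. The arrays with the narrowest ranges were the lowest among KO hosts but the highest among wild-type hosts (8.48 and 8.29 in hosts 2 and 5). A relation to spread that differs between the groups is therefore not excluded. A less oxygenated tumour in hosts without p62 is a possible explanation that was not tested, since tumour size and necrosis are not in the labels.

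KO hosts 2 and 3, at 5.75 and 5.40 in Nlrp1c-ps, lay above their group mean of 5.33, so that they make the difference smaller. Without them it was -1.80. This outcome was fixed by these values, and groups that did not overlap before could not overlap then. It is therefore no separate test. Sqstm1 and the Nlrp1 genes lie on the same chromosome, so that a segment of another strain carried along with the knockout could lower the signal of probes on variant bases. Of the 368 measured genes between them, 1 had an unadjusted p under 0.01, a share of 0.272% that equals the median of 11910 windows of as many genes and lies at percentile 32.9. The bound first written would have excluded the explanation at or below that median, which was wrong because a share equal to the median is not below it by any spread, and a segment need not alter the genes between. A strain segment, a host effect and signal shared among Nlrp1 copies cannot be told apart, as the labels do not give the origin of the knockout.

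A hypothesis that Il6 follows hypoxia within tumours was tested as 1 relation. Across the 12 tumours Il6 and the hypoxia list had a Spearman's rho of 0.629 (permutation p = 0.0334) and a Pearson's r of 0.662 (permutation p = 0.018). Within KO hosts rho was 0.714 (exact permutation p = 0.136) and within wild-type hosts 0.371 (exact permutation p = 0.497). Without KO hosts 5 and 6, the farthest from the median in hypoxia, r was 0.469 (permutation p = 0.174). Leaving out KO host 6 alone, the tumour highest in both, gave an r of 0.394 (permutation p = 0.232), and leaving out KO host 5 alone gave 0.746 (permutation p = 0.0102), so that r did not pass without KO host 6. Over all leave-outs, made after the relation was seen, rho lay between 0.518 and 0.8, at permutation p of 0.00482 to 0.106.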
